A study of Mus musculus with 4 samples.

How the data were processed

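Total RNA from 4 B cell cultures, 2 without and 2 with 10 mM sodium acetate, was hybridised to whole-genome Affymetrix mouse expression arrays, 1 array per sample. Per the labels, biotin-labelled cRNA was made from 2 ug of total RNA. Whether dendritic cells were removed before the RNA was taken is not given in the sources used here.

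The deposited values are array intensity on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The scaling target, background step and detection calls are not given in the sources used here. The deposited table holds 45101 probe sets per array, 64 of them control sets that were kept out of the tests. Medians of the 4 columns were 14.1 for control 1, 15.9 for acetate 1, 13.5 for control 2 and 10.9 for acetate 2. The trimmed means, leaving out 2% at each end, differed 2.02-fold between the highest and lowest array, so no scaling to a common trimmed mean shows in the values. The hybridisation spike-ins bioB, bioC, bioD and cre agreed within 1.10-fold between arrays.

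Values were analysed as log2(value + 32). Fold changes are on this scale, which understates changes of dim genes. The rule set before the data were examined was to quantile normalize where trimmed means differed by over 10%, and this applied. Probe sets with a mean in the upper 50% were kept, 22519 of 45037. The platform annotation gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160; of the first, 34741 were matched to the mouse RefSeq annotation (GRCm38.p6) to update symbols. Probe sets with several genes or none were named for no gene. No coordinates are given, since the labels name no build. For a gene with several probe sets the one with the highest mean was used, which left 11165 genes.

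Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. A size rule counted genes in which both acetate arrays lay at least 2-fold above or below both controls. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, with camera using an estimated correlation, and with fry; 29 of 30 lists had at least 5 measured genes. The list of short-chain fatty acid receptors and transporters had fewer and was not tested. The lists overlap: Jchain stands in the immunoglobulin and plasma cell lists, and Xbp1, Creld2 and Edem1 in the plasma cell and unfolded protein response lists.

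The genes named in the text follow a rule. First came 10 genes per direction, past the threshold or, where too few passed, those with the smallest unadjusted p among genes whose groups did not overlap and whose log2 difference was at least 1. To these were added fixed key genes and up to 4 genes with the smallest p in each list described. Predicted genes, unnamed clones and immunoglobulin variable genes were passed over in the first part, which left out 1 gene, Igkv14-111. Of 16 key genes 13 were measured; Aicda, Cd19 and Ighg1 were not represented by a named probe set past the filter. Some genes named in the text fall outside the rule and were chosen after their values were seen: Cr2, Igha, Iglv1, S100a8, Ngp, Il12a, Cd5l, Fscn1 and Vcam1.

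The array numbers in the titles recur in both groups. Sex-linked genes, fixed as a check before the data were examined, separated number 1 from number 2 arrays, and deviations of same-numbered arrays from their group means correlated at 0.60 across genes, which are not independent replicates. The labels do not say what the numbers stand for, so the comparison over all arrays remained the first analysis, and the fit with the number as a term, planned beforehand, is given beside it because the number follows sex. That fit leaves 1 residual degree of freedom and relies on the spread shared across genes.

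The steps were tested on simulated data with 11165 genes. At the spread fitted over all arrays, limma recovered 8% of changes of 1 log2 unit and 88% of changes of 2 log2 units, with 4 false calls; with the number as a term it recovered 91% and 100%, with 14 false calls. A simulated list shift of 0.5 was recovered by camera, with 0 other lists called. The simulated genes varied independently, whereas the shifted list, the unfolded protein response, had an estimated correlation of 0.57 in the real arrays. The simulation therefore does not show how often camera at the preset correlation calls lists falsely here.

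Alternatives covered pseudocounts of 1 and 100, no filter and a stricter filter, centring on medians, no variance trend, the number as a block, the mean over probe sets, only probe sets specific to a gene, every probe set tested, limma treat at a fold of 1.5, and leaving out each array. After the data were seen, values without normalization and a fit with the log2 Actb 3' over 5' ratio as a covariate were added. Camera with an estimated correlation within each setting was added then too. That form of camera rests on the residual degrees of freedom. With the number as a term, the covariate or an array left out, 1 is left. Where calls are lost there, the loss argues neither against a list nor for it.

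The lists not described elsewhere did not pass camera over all arrays. Adjusted p-values were 0.0746 for histone deacetylases and acetyltransferases, 0.0926 for the tricarboxylic acid cycle, 0.120 for lysosome and autophagy, 0.210 for the NRF2 response, 0.254 for erythroid and platelet markers and 0.309 for T cell markers. They were 0.488 for fatty acid oxidation, 0.658 for hypoxia, 0.737 for type I interferon, 0.948 for amino acid starvation, 0.994 for apoptosis regulators and 0.996 for NK and innate lymphoid markers. Of these, the tricarboxylic acid cycle, histone, erythroid and platelet, T cell, fatty acid oxidation, type I interferon and amino acid starvation lists passed under at least 1 alternative setting at the preset correlation. With an estimated correlation camera called 0 lists in each of these settings.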

Results

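Gene expression was measured in cultures of mouse B cells that had been activated without or with sodium acetate, the salt of a short-chain fatty acid. CD19-positive cells from C57BL/6 spleen were stimulated through the B cell receptor with an antibody against IgM. Mature dendritic cells grown from bone marrow were present, at 2 B cells for each dendritic cell, and the cultures ran for 5 days. There were 2 control arrays and 2 arrays from cultures with 10 mM acetate, numbered 1 and 2 in each group. Nothing in the labels says that the arrays came from separate animals. Sex-linked genes, given below, show that numbers 1 and 2 came from cells of different sex, so not from the same animals. Within a number, nothing shows separate animals for acetate and control. Over all arrays the p-values measure the spread between these 4 arrays, which holds the difference between the numbers, and part of which may be technical. The number of arrays limits the precision of every value.

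The deposited signal differed between arrays before normalization. The trimmed mean intensity was 134 in control 1, 123 in acetate 1, 87.3 in control 2 and 66.6 in acetate 2. Signal at the 3' end of the Actb transcript over that at its 5' end, a measure of how far labelling reached along a transcript, was 2.35 in control 1 and 5.02 in acetate 1. It was 4.50 in control 2 and 7.93 in acetate 2, so both acetate arrays lay above the control of the same number. The same ratio for the bacterial dap spike-in was 3.74, 12.9, 10.1 and 25.8 in that order of arrays. The last is not exact, since its 5' signal, 8.73, lay under the median of acetate 2, 10.9. The array numbers also carried a sex difference. The Y-linked gene Eif2s3y had deposited intensities of 282 and 349 in the number 1 arrays against 0.42 and 0.30 in the number 2 arrays, and Xist, expressed from the inactive X chromosome, had 20.5 and 12.1 against 6939 and 5476. Effects of acetate are therefore given over all arrays and also with the array number as a term, which compares acetate with control within each sex.

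**Figure D1:**
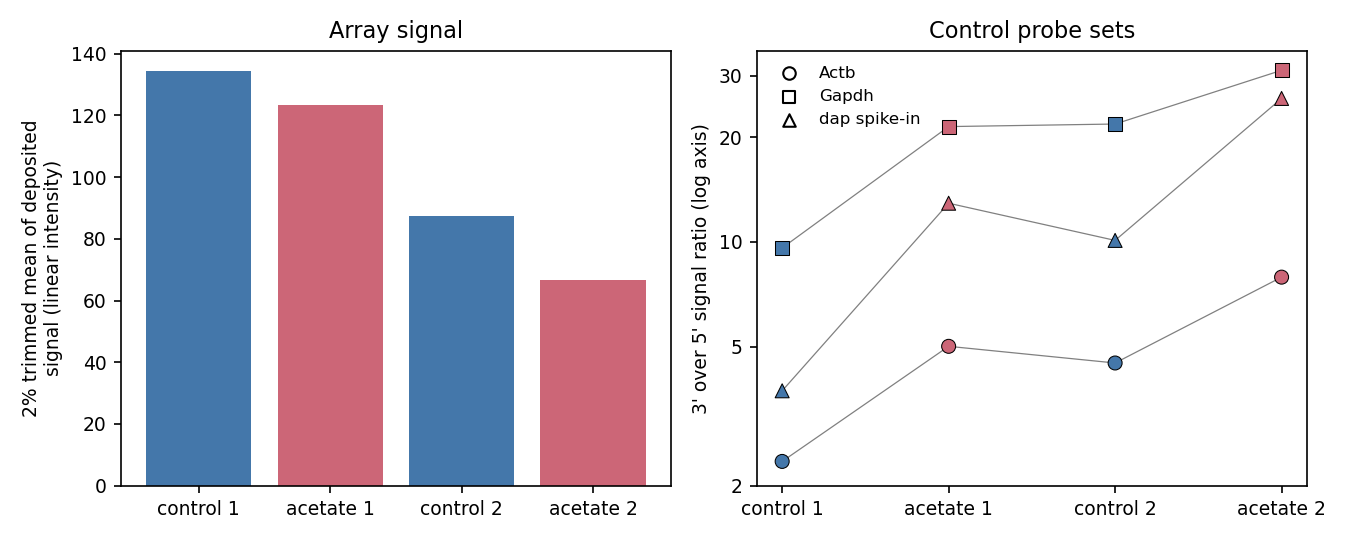
Bars (left) show the 2% trimmed mean of the deposited linear intensity of each array, and points (right) show the 3' over 5' signal ratio of Actb, Gapdh and the dap spike-in on a log axis, with controls in blue and acetate in red. The Actb ratio is 2.35 and 4.50 in the controls and 5.02 and 7.93 in the acetate arrays.

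The comparison of acetate with control asks which transcripts of the cultures differ when acetate is present. The RNA was not of B cells alone. The macrophage markers Lyz2 and Mmp12 had mean log2 values of 13.0 and 11.8 over the arrays, against 13.6 for Ighm. Differences are therefore not assigned to a cell type. Several transcripts known from antibody-secreting cells had higher means with acetate, none past the limma threshold over all arrays (smallest adjusted p 0.230). Ighg3, the IgG3 heavy chain, was 7.02-fold higher (log2 difference 2.81, SE 0.39, n = 2 arrays per group), and Jchain, which joins IgM and IgA into polymers, was 4.74-fold higher (2.24, SE 0.28). Prdm1, which encodes the plasma cell regulator Blimp-1, was 5.09-fold higher (2.35, SE 0.47), and Eaf2, an elongation factor-associated gene of the plasma cell list, was 4.44-fold higher (2.15, SE 0.32). Spib, a transcription factor of B cells, was 2.30-fold lower (-1.20, SE 0.16), and Cd27, a costimulatory receptor of the TNF receptor family, was lower (-1.54, SE 0.20). Cd27 had deposited intensities of 158 and 109 in the controls against 20.04 and 16.2 with acetate, the latter near the array medians of 10.9 to 15.9, so the size of its difference depends on the pseudocount of 32.

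Across the 11165 genes tested, limma called 0 genes at an adjusted p of 0.05 over all arrays, with a smallest adjusted p of 0.230. At an unadjusted p under 0.05 there were 1055 genes, 493 higher and 562 lower. Chance would give 558 if the arrays were independent, but the split of the same arrays by number gave 1331 and the crossed split 35. With the array number as a term, limma called 980 genes, 418 higher and 562 lower, on 1 residual degree of freedom. Both acetate arrays had higher 3' over 5' ratios than the control of the same number, so the number term leaves labelling aligned with acetate. With the Actb 3' over 5' ratio as a covariate in its place, limma called 486 genes, 243 higher and 243 lower. Without acetate 1 it called 145 genes and without acetate 2 it called 17, the lone array of a group being assumed to vary like the others. In 24 genes both acetate arrays lay at least 2-fold above both controls, and in 21 both lay at least 2-fold below. All 45 passed with the array number as a term, which is no separate support, since the size rule used the same arrays. These counts moved with single arrays and with the pseudocount: 121 higher without acetate 1 and 192 lower without control 2 (47 to 121 and 39 to 192 without single arrays), 89 and 72 at a pseudocount of 1, and 7 and 4 at 100. The split of the arrays by number gave 28 such genes and the crossed split gave 0. Without the size rule, 23.3% of genes were separated upward and 17.3% downward. Chance would give 33.3% for both directions together if the arrays were independent. Arrays of the same number were correlated, so that share is no firm benchmark here.

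The 10 genes with the strongest evidence of a higher level ranged from 1.29 to 2.81 in log2 difference, and the 10 with the strongest evidence of a lower level from -1.94 to -1.20. None passed over all arrays (limma adjusted p from 0.230 to 0.250), and all 20 passed with the array number as a term (limma adjusted p from 0.000271 to 0.00561). The 20 were picked in these same arrays for separated groups and a small p, so the latter result is no separate support. Besides Ighg3, Jchain and Eaf2, the higher genes included Lcn2, an iron-siderophore binding protein (2.26, SE 0.24), Tg, the thyroglobulin gene (2.27, SE 0.34), Steap4, a metalloreductase (1.82, SE 0.23), and Cxcl2, a neutrophil-attracting chemokine (1.29, SE 0.20). Ptgr1 (1.62), Igsf5 (1.44) and Tmem255a (1.36) completed them. The lower genes included Cst6, a cysteine protease inhibitor (-1.94, SE 0.25), Gabarap, an autophagy protein (-1.92, SE 0.25), Apoe, a lipid carrier (-1.53, SE 0.25), and Nfkb2, a subunit of the alternative NF-kB pathway (-1.36, SE 0.21). Pstpip2 (-1.61), Acin1 (-1.60), Sh2b2 (-1.46) and Efnb1 (-1.41) made up the rest, beside Spib and Cd27. In 8 of the 20, both arrays of the lower group had deposited intensities under the pseudocount of 32, so their sizes are not exact: Lcn2, Steap4, Cxcl2, Igsf5, Tmem255a, Cst6, Efnb1 and Cd27. Lcn2 had 1.99 and 14.1 in the controls against 216 and 90.0 with acetate, and its difference was 4.52 at a pseudocount of 1 and 1.27 at 100; for Cd27 these were -2.54 and -0.87. The dimmer probe sets of Efnb1 were at -0.74 and -0.12 (SE 0.23 and 0.19) and those of Pstpip2 at -1.07 and -0.52 (SE 0.26 and 0.17).

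**Figure D2:**
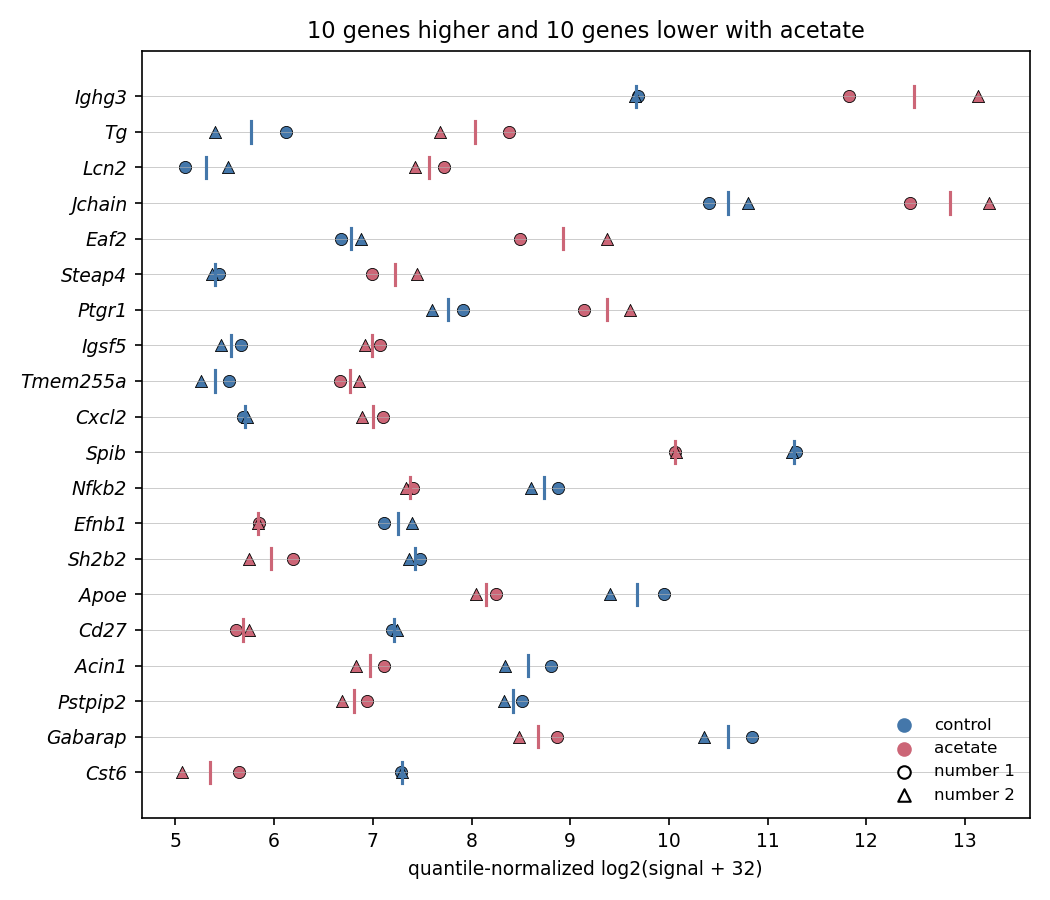
Quantile-normalized log2(signal + 32) of 10 genes higher and 10 genes lower with acetate, 1 point per array (blue control, red acetate, circles number 1, triangles number 2) and vertical bars at the group means. Differences of the means run from -1.94 for Cst6 to 2.81 for Ighg3, and in each gene both acetate arrays lie on one side of both controls.

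The immunoglobulin list, which holds Jchain beside heavy and light chain genes and leaves out most variable-region genes, had 6 measured members, all with a positive difference and a median of 1.69 (camera adjusted p = 7.37e-07; adjusted p = 0.873 with an estimated correlation). Beside Ighg3 and Jchain these were Igha, the IgA heavy chain (1.96, SE 0.66), Igk (1.43, SE 0.25), Iglv1 (0.50, SE 0.42) and Ighm, the IgM heavy chain (0.46, SE 0.12). All 6 passed with the array number as a term, and 5 passed over all arrays when adjusted over the list alone. The median was 0.96 between the number 1 arrays and 2.17 between the number 2 arrays, and without control 2 it was 1.12, still past the threshold. The probe sets of Ighm disagreed in size, from -0.0040 in a set close to background (mean 5.91 on the log2 scale) to 2.89. The other sets of Igk were at 2.03 (SE 0.44) and -0.043 (SE 0.30).

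The plasma cell list, with 27 measured genes, had a median of 0.70 (camera adjusted p = 9.39e-05; adjusted p = 0.873 with an estimated correlation). In the fit with the array number 12 of its genes rose, 1 fell and 14 did not pass, and 5 passed when adjusted over the list alone. Xbp1, a regulator of secretory capacity, was at 1.09 (SE 0.33) and Creld2 at 1.29 (SE 0.33), while Zbtb20 was the gene that fell (-1.17, SE 0.21), its 7 dimmer probe sets lying between -1.19 and -0.19. Sdc1, the surface protein CD138, was at 0.67 (SE 0.34) and Irf4 at 0.40 (SE 0.23). The list median was 0.30 between the number 1 arrays and 0.93 between the number 2 arrays. With the 3' over 5' ratio as a covariate it was 0.30 and lost the call (camera adjusted p = 0.122), and without acetate 2 it was 0.39, still past the threshold.

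Genes of the unfolded protein response, which expands protein folding in the endoplasmic reticulum, had a median of 0.46 over 35 measured members (camera adjusted p = 2.23e-06; adjusted p = 0.901 with an estimated correlation). Of these, 16 rose, 0 fell and 19 did not pass with the array number as a term, and 8 passed when adjusted over the list alone. Among them were the disulfide isomerase Pdia4 (1.16, SE 0.28) and the chaperones Hsp90b1 (1.07, SE 0.29) and Dnajb11 (0.98, SE 0.25). The probe sets of Hsp90b1 disagreed, a second one with a mean of 9.23 on the log2 scale being at -0.025 (SE 0.25). The median was 0.29 between the number 1 arrays and 0.76 between the number 2 arrays; it was 0.22 without acetate 2 and 0.81 without acetate 1, past the threshold in both. It moved with the 3' over 5' ratio, and with that ratio as a covariate it was 0.092 (camera adjusted p = 0.265).

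The ribosome biogenesis and MYC list was lower, with a median of -0.25 over 37 measured genes (camera adjusted p = 9.66e-05; adjusted p = 0.966 with an estimated correlation). Of its genes, 8 fell, 0 rose and 29 did not pass with the array number as a term, and 0 passed when adjusted over the list alone. The RNA polymerase I subunit Polr1a was at -1.004 (SE 0.30), Ppan at -1.03 (SE 0.38), nucleolin, Ncl, at -0.47 (SE 0.16) and Myc at -0.59 (SE 0.28). Probe sets differed in size: the other sets of Ncl were at -0.96, -0.021 and -0.16, and those of Polr1a at 0.069 and -0.56. The median was -0.18 between the number 1 arrays and -0.30 between the number 2 arrays. With the 3' over 5' ratio as a covariate its direction turned, to 0.15, and without acetate 2 it was -0.036 and without control 1 -0.12, both past no threshold (camera adjusted p = 0.269 and 0.122).

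B cell identity genes went both ways, with a median of -0.12 over 27 measured genes (camera adjusted p = 0.0423; adjusted p = 0.873 with an estimated correlation). Within it, 9 fell, 4 rose and 14 did not pass with the array number as a term, and 9 passed when adjusted over the list alone; the list itself was then past no threshold (camera adjusted p = 0.0879), nor was it without acetate 1 (-0.049, camera adjusted p = 0.167) or without control 2 (-0.19, camera adjusted p = 0.429). It was lower with the 3' over 5' ratio as a covariate (-0.47, camera adjusted p = 0.000286), without control 1 (-0.28, camera adjusted p = 0.00184) and without acetate 2 (-0.28, camera adjusted p = 3.83e-05), but these calls were lost (camera adjusted p = 0.636, 0.814 and 0.873 with an estimated correlation). Those that fell included the tetraspanin Cd37 (-1.41, SE 0.25), the receptor component Cd79a (-0.97, SE 0.20), the chemokine receptor Ccr6 (-1.41, SE 0.33) and Pax5, the B lineage regulator (-0.74, SE 0.21), of which a dimmer probe set was at 0.026 (SE 0.20). The complement receptor Cr2 rose (0.86, SE 0.23). The median was -0.10 between the number 1 arrays and -0.15 between the number 2 arrays. Bach2, a repressor of plasma cell differentiation, was at -0.01 (SE 0.26) and Bcl6, of germinal centre cells, at 0.39 (SE 0.21).

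The granulocyte and mast cell list had 6 measured genes and a median of 0.40 (camera adjusted p = 0.0159; adjusted p = 0.873 with an estimated correlation). When the array number was a term, 2 rose, Lcn2 and the collagenase Mmp8 (1.80, SE 0.35), and 4 did not pass; the same number, 2, passed when adjusted over the list alone. The granulocyte gene S100a8 was at 0.31 (SE 0.24), Ngp at 0.28 (SE 0.26), Gata2 at 0.49 (SE 0.26) and Kit at -0.48 (SE 0.26). The median was 0.55 between the number 1 arrays and 0.61 between the number 2 arrays, and with the 3' over 5' ratio as a covariate it was 0.096 (camera adjusted p = 0.0548). Without control 2 it was 0.55 and not past the threshold (camera adjusted p = 0.0675). The list rests on dim genes, Lcn2, Ngp, Gata2 and Kit having both arrays of a group under 32, and its median was 0.94 at a pseudocount of 1 and 0.20 at 100. With no filter on dim probe sets it was 0.048 and lost the call (camera adjusted p = 0.216).

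Markers of the other cells in the cultures did not pass as lists over all arrays. Dendritic cell markers had a median of -0.06 but a mean of 0.10 over 22 genes (camera adjusted p = 0.552, direction lower), and macrophage and monocyte markers -0.12 over 28 genes (camera adjusted p = 0.488). With the 3' over 5' ratio as a covariate both turned to higher and passed, at 0.40 (camera adjusted p = 0.000286) and 0.42 (camera adjusted p = 0.0149), but not in that fit with an estimated correlation (camera adjusted p = 0.636 with an estimated correlation for both). The dendritic cell list also passed in opposite directions without control 1 (0.15, camera adjusted p = 0.0341) and without control 2 (-0.23, camera adjusted p = 0.0312), where camera gave adjusted p = 0.814 and 0.945 with an estimated correlation. With the array number as a term 2 dendritic cell markers rose, Tmem176a (1.75, SE 0.48) and Tmem176b (2.04, SE 0.77), 3 fell, among them Cd40 (-0.85, SE 0.25) and Ccl22 (-0.63, SE 0.19), and 17 did not pass. In the macrophage list 4 rose, among them the arginase Arg1 (2.20, SE 0.60, both controls under 32), 4 fell, among them Apoe and Trem2 (-1.33, SE 0.36), and 20 did not pass. Itgax, the dendritic cell integrin CD11c, was at 0.13 (SE 0.27). When adjusted over the list alone, 0 dendritic cell markers and 1 macrophage marker passed.

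Lists on the use of acetate and on energy metabolism did not pass over all arrays. The acetate use and fatty acid synthesis list had a median of 0.07 over 25 genes (camera adjusted p = 0.948); with the array number as a term 1 rose, the desaturase Scd2 (1.11, SE 0.22; dimmer probe sets at 0.0098 and -0.59), 1 fell, the fatty acid synthase Fasn (-0.74, SE 0.23), and 23 did not pass. Acss2, which makes acetyl-CoA from acetate, was at 0.14 (SE 0.19), and the short-chain fatty acid receptor Ffar2 at 0.43 (SE 0.22). Glycolysis had a median of -0.04 over 20 genes (camera adjusted p = 0.488), of which 1 fell with the array number as a term, Pfkl (-0.95, SE 0.34; dimmer probe sets at -0.95 and -0.079), and 19 did not pass; Hk2 was at 0.29 (SE 0.23). Oxidative phosphorylation had a median of 0.12 over 68 genes (camera adjusted p = 0.0690), of which 2 rose, 2 fell and 64 did not pass with the array number as a term. Ndufv3 was at 0.55 (SE 0.15) and Atp5g2 at -0.92 (SE 0.19). This list passed with the 3' over 5' ratio as a covariate (0.30, camera adjusted p = 3.17e-05), with the mean over probe sets (0.11, camera adjusted p = 0.0439), without control 1 (0.17, camera adjusted p = 0.0250) and without acetate 2 (0.22, camera adjusted p = 1.69e-05). In the same settings camera gave adjusted p = 0.658, 0.911, 0.857 and 0.873 with an estimated correlation. When adjusted over the list alone, the acetate list had 1 passing gene and the other lists named here 0.

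The cell cycle list had a median of 0.18 over 47 genes and did not pass over all arrays (camera adjusted p = 0.0617). With no filter on dim probe sets it passed, but not there with an estimated correlation. It passed with the array number as a term (camera adjusted p = 0.0192; adjusted p = 0.787 with an estimated correlation), where 5 genes rose, 3 fell and 39 did not pass. The proliferation marker Mki67 was at 0.82 (SE 0.23), cyclin E1, Ccne1, at 0.81 (SE 0.24) and the ribonucleotide reductase subunit Rrm2 at 0.74 (SE 0.29), with other probe sets of Rrm2 at 0.60 (SE 0.36) and -0.14 (SE 0.44) and of Ccne1 at 0.17 (SE 0.29); 0 passed when adjusted over the list alone. The list was at 0.74 with the 3' over 5' ratio as a covariate (camera adjusted p = 4.53e-17), at 0.42 without control 1 (camera adjusted p = 1.64e-06) and at 0.43 without acetate 2 (camera adjusted p = 3.5e-09), but turned to -0.053 without acetate 1 and -0.044 without control 2. The calls in the covariate fit, without control 1 and without acetate 2 were lost when the correlation was estimated (camera adjusted p = 0.636 in the covariate fit). Each of these fits leaves 1 residual degree of freedom, so the loss argues neither against the list nor for it.

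**Figure D3:**
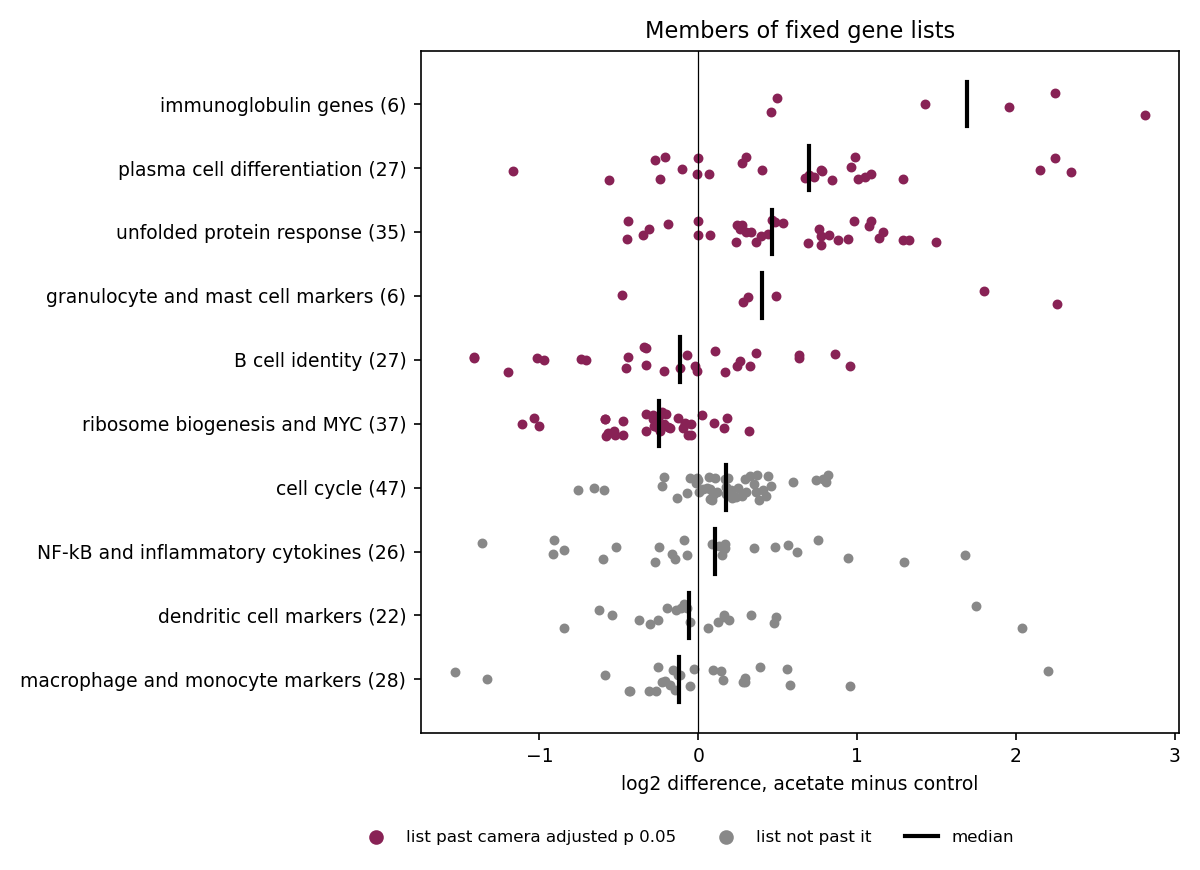
Log2 difference, acetate minus control, of each measured member of 10 gene lists (number of genes in brackets), 1 point per gene, with a black bar at the list median; points are purple where the list passed camera at an adjusted p of 0.05 and grey where it did not. Medians run from 1.69 for the immunoglobulin genes to -0.25 for ribosome biogenesis and MYC, a list that turns to 0.15 with the 3' over 5' ratio as a covariate; the cell cycle, dendritic cell, macrophage and NF-kB medians also turn under other settings.

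Of 29 lists tested, camera called 6 at a preset correlation of 0.01, 4 higher and 2 lower; 0 held with an estimated correlation and 0 were called by fry. Under each of the 15 other settings, too, camera called 0 lists with an estimated correlation. That test lost calls even where the estimated correlation was negative. The granulocyte list, at -0.14, went from a camera p of 0.00275 at the preset correlation to 0.0918. Over all arrays 2 residual degrees of freedom were left, and 1 with a further term or an array left out. The lack of calls therefore does not argue against a list, nor for it. In the other called lists the estimate exceeded the preset 0.01. It was 0.46 for immunoglobulin genes, 0.57 for the unfolded protein response and 0.31 for the plasma cell list. For ribosome biogenesis it was 0.65 and for B cell identity 0.024. If these estimates hold, the p-values at the preset correlation are too small.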

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

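All weighing tests in this part were chosen after the results were seen. They are the fit with the 3' over 5' ratio as a covariate and the comparison of acetate 1 with control 2. The comparisons with B cell identity genes and with abundant dendritic cell and macrophage markers belong to them too.

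Among 3292 probe sets with no single gene name, which the comparisons leave out, 8 had both acetate arrays at least 2-fold above both controls and 3 had both at least 2-fold below. The log2 3' over 5' ratio of the dap spike-in was 1.57 higher in the acetate arrays than in the controls. The size is not exact, since the 5' signal of dap in acetate 2, 8.73, lay under the median of that array, 10.9. This spike-in is not made by the cells, so its ratio reflects labelling or the RNA handling after it was added.

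The immunoglobulin, plasma cell and unfolded protein response lists had higher medians with acetate, 1.69, 0.70 and 0.46, though with an estimated correlation none passed (camera adjusted p = 0.873, 0.873 and 0.901). For the immunoglobulin genes the median was 1.39 with the ratio as a covariate and 1.40 between acetate 1 and control 2. Those 2 arrays had similar ratios, so the ratio does not by itself account for the gap between them. But both values rest largely on that pair, a single array per group. Of the 6 genes, 2 meet the size rule, which fixes their direction in it. The central 95% of 10000 random lists of like expression ran from -0.31 to 0.30 in that pair. Random lists lack the estimated correlation of 0.46 within this list, and the range holds no spread between replicate arrays. Uneven 3' labelling is thus not excluded. For the plasma cell list uneven labelling cannot be told apart from acetate. With the covariate that list was at 0.30 and lost its call, yet it lay at the 99.6th percentile of random lists in that pair of arrays. The percentile has the same limits, the estimated correlation of the list being 0.31. Uneven labelling may account for the unfolded protein response list, at 0.092 with the covariate. The array number may also account for the lower values, since number 2 minus number 1 medians were 0.42 for the plasma cell list and 0.33 for the unfolded protein response list. A larger share of B cells in an unchanged state would raise the B cell identity genes too. Over all arrays their median was -0.12 and their upper quartile 0.25, under the plasma cell median of 0.70. With the covariate the identity median was -0.47 and the plasma cell median 0.30. This comparison was chosen after both lists had been seen, so it is no independent test of that share. A larger share of B lineage cells that had lost identity genes was not tested. Sex was balanced between the groups, and the immunoglobulin median was 0.96 within number 1 and 2.17 within number 2. A response of the B cells to acetate stays open as a hypothesis for the immunoglobulin genes, as do uneven labelling and differences between single cultures.

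The ribosome biogenesis and MYC list was lower with acetate by a median of -0.25. Uneven 3' labelling may account for this, since with the ratio as a covariate the median turned to 0.15. Between acetate 1 and control 2 it was 0.11. The array number may account for that turn instead, the number 2 minus number 1 median of this list being -0.43. Acetate minus control was -0.18 within number 1 and -0.30 within number 2. A response to acetate was not separated from uneven labelling.

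Lcn2, Mmp8, Il1b and Cxcl2, a group put together after the values were seen, were higher with acetate by a median of 1.74. Uneven 3' labelling cannot be told apart from acetate for them: their median was 2.13 with the ratio as a covariate, but all 4 have acetate 1 at least 2-fold above control 2, a difference fixed by how they were picked and one that the covariate value follows (2.15 between those arrays). A larger share of dendritic cells and macrophages in an unchanged state was not decided. Over all arrays the 10 most abundant of their markers did not rise as a set, with a largest difference of 0.39 and a median of -0.16. With the covariate these were 1.12 and 0.16. The smallest of the 4 genes was at 1.29, or 1.36 with the covariate. But the 4 were picked for being high, so the gap to the markers is partly fixed. Other values go with a myeloid source: with the covariate the dendritic cell and macrophage lists were at 0.40 and 0.42 (camera adjusted p = 0.000286 and 0.0149; adjusted p = 0.636 with an estimated correlation for both), and Arg1 (2.20), Tmem176b (2.04) and Tmem176a (1.75) exceeded 1.29. These genes were named for exceeding 1.29, and other members of both lists fell, among them Apoe (-1.53), Trem2 (-1.33) and Cd40 (-0.85). With the array number as a term, 4 macrophage markers rose and 4 fell, and 2 dendritic cell markers rose and 3 fell. A larger share, a change of state or a larger subset among dendritic cells and macrophages stays open and may be followed up. So does a small number of granulocytes, although S100a8 was at 0.31.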

How the results depend on the processing

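The unnormalized values and the ratio covariate were chosen after the data were seen. Of 1317 alternatives over 90 named genes, 1145 kept direction and side of the threshold, 159 gained a call and 13 turned direction; of 287 over 17 lists, 215 kept both, 15 gained a call, 28 lost it and 29 turned. The cause was not tested for the changes below, except that leaving out an array means fewer samples.

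Genes called by limma numbered 16 as deposited, 486 with the ratio covariate, 1 to 145 without single arrays (145 without acetate 1, 17 without acetate 2) and 0 under the other settings without a block. With the array number as a replicate block, the paired form of the fit, limma called 980, against 1055 and 2795 genes at an unadjusted p under 0.05 without and with it. Genes at least 2-fold higher numbered 89 at a pseudocount of 1, 7 at 100, 14 as deposited and 47 to 121 without single arrays (121 without acetate 1); those lower numbered 72, 4, 13, 13 with the mean over probe sets and 39 to 192 (192 without control 2). The median difference of all genes was -0.16 as deposited and 0.10 with median centring, against 0.04.

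Called lists numbered 0 with an estimated correlation, 0 by fry, 13 with the covariate and 5 to 11 without single arrays (11 without control 1, 10 without acetate 2). An estimated correlation and fry ended all 6 calls at medians of 1.69, 0.46, 0.70, -0.25, 0.40 and -0.12 (adjusted p 0.873 and 0.398 for immunoglobulin genes). The covariate ended those of the unfolded protein response (0.092), plasma cell (0.30) and granulocyte (0.096) lists. The granulocyte call also ended with no filter (0.048). That of B cell identity ended with no filter (-0.14), median centring (-0.12), as deposited (-0.38), with no variance trend, the replicate block or the mean over probe sets (-0.12 each) and with specific probe sets (-0.095).

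Without single arrays, medians ranged from 1.12 (without control 2) to 1.82 for the immunoglobulin list, 0.39 (without acetate 2) to 1.002 (without acetate 1) for the plasma cell list and 0.22 (without acetate 2) to 0.81 (without acetate 1) for the unfolded protein response, all called. They ranged from -0.46 to -0.036 for ribosome biogenesis (call lost without control 1, at -0.12, and acetate 2, at -0.036), 0.27 to 0.62 for granulocyte genes (lost without control 2, at 0.55) and -0.28 to -0.049 for B cell identity (lost without acetate 1, at -0.049, and control 2, at -0.19). Directions turned within -0.053 to 0.43 for the cell cycle, -0.26 to 0.20 for NF-kB, -0.34 to 0.080 for MHC class II and -0.11 to 0.12 for the germinal centre list, each without acetate 1 and without control 2. They turned within -0.23 to 0.20 for macrophage, -0.23 to 0.15 for dendritic cell and -0.20 to 0.19 for glycolysis genes, each without control 1 and without acetate 2. The ranges were -0.020 to 0.12 for acetate use and -0.23 to 0.43 for Itgax (turned without control 2), and -0.33 to 0.31 for Bach2 (turned without acetate 1 and control 2).

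Directions turned with the covariate for ribosome biogenesis (0.15), macrophage (0.42), dendritic cell (0.40) and glycolysis (0.25) lists and for Myc (0.058), Rrp9 (0.014), Gata2 (-0.069) and Kit (0.084). As deposited they turned for the cell cycle (-0.062), oxidative phosphorylation (-0.053), NF-kB (-0.15), acetate use (-0.13), cholesterol (-0.090) and germinal centre (-0.14) lists, Hk2 (-0.0041) and Itgax (-0.15). No filter turned acetate use (-0.0051) and germinal centre (-0.0031), the mean over probe sets germinal centre (-0.083) and Bach2 (0.0021), and median centring dendritic cells (0.067) and Bach2 (0.00052). Specific probe sets turned Fdft1 (-0.013) and gave -0.0040 for Ighm, there from a set close to background (mean 5.91) that shows no direction of that transcript. Dim genes near the pseudocount are limited by signal over background.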

Other observations

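The gene groups in this part were fixed before the data were examined; the genes that separate the array numbers were picked after their values were seen.

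Regulatory B cell genes moved both ways. The list of 19 measured genes had a median of 0.26 and did not pass (camera adjusted p = 0.210), while 5 members passed when adjusted over the list alone, and with the array number as a term 4 rose, 3 fell and 12 did not pass. Il10, the cytokine by which these cells are often defined, was at 0.98 (SE 0.20, both controls under the pseudocount of 32), the inhibitory receptor Ctla4 at 1.14 (SE 0.21) and Cd24a at 0.85 (SE 0.19), whereas Havcr1, the surface marker Tim-1, was at -1.89 (SE 0.31) and Il12a, a subunit of interleukin-35, at -0.82 (SE 0.20). The NF-kB and inflammatory cytokine list of 26 genes had a median of 0.11 (camera adjusted p = 0.958) with 8 passing when adjusted over the list alone; with the array number as a term 5 rose, 6 fell and 15 did not pass. With the 3' over 5' ratio as a covariate that list passed at 0.35 (camera adjusted p = 0.0202; adjusted p = 0.636 with an estimated correlation), while without control 2 it was at -0.26. Il1b was at 1.68 (SE 0.27) and Cxcl2 at 1.29 (SE 0.20), against Nfkb2 at -1.36 (SE 0.21) and Nfkbie at -0.91 (SE 0.20).

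Antigen presentation genes of the MHC class II list had a median of -0.12 over 14 genes (camera adjusted p = 0.0746), of which 4 fell, 0 rose and 10 did not pass with the array number as a term; Ifi30 was at -0.81 (SE 0.16), H2-DMa at -0.67 (SE 0.18) and the transactivator Ciita at -0.71 (SE 0.20), and 1 passed when adjusted over the list alone. The MHC class II list passed with the covariate (-0.59, camera adjusted p = 3.09e-06), with the mean over probe sets (-0.19, camera adjusted p = 0.0139), without control 1 (-0.26, camera adjusted p = 0.000876) and without acetate 2 (-0.34, camera adjusted p = 2.48e-05), and turned to 0.080 without acetate 1 and 0.044 without control 2. These 4 calls were lost when the correlation was estimated (camera adjusted p = 0.636 with the covariate and 0.835 with the mean over probe sets). With 1 or 2 residual degrees of freedom, that loss argues neither against the list nor for it. Cholesterol synthesis had a median of 0.18 over 20 genes (camera adjusted p = 0.337), of which 3 rose, 2 fell and 15 did not pass with the array number as a term; Srebf2 was at -0.85 (SE 0.22) and Sqle at 0.57 (SE 0.20). The germinal centre and class switching list had 25 genes, 13 with a positive and 12 with a negative difference (camera adjusted p = 0.702), of which 0 rose, 3 fell and 22 did not pass with the array number as a term; Cd83 was at -0.62 (SE 0.14). In both lists 0 passed when adjusted over the list alone.

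Arrays of number 2 differed from those of number 1 beyond the sex-linked genes. With acetate and control pooled, limma called 3 genes between the numbers: Xist, Eif2s3y and Cd5l, a secreted macrophage protein, which was higher in number 2 by 2.75 (limma adjusted p = 0.0394). Fscn1, a dendritic cell marker, was at -2.74 (limma adjusted p = 0.0794) and the adhesion molecule Vcam1 at 2.12 (limma adjusted p = 0.0847), neither past the threshold.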
